A study of Mus musculus with 16 samples.

How the data were processed

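RNA from bone marrow cells of C57BL/6 mice purified by fluorescence-activated sorting was sequenced after amplification with the SMART-Seq v4 kit, per the labels. The 16 libraries fell into 6 groups taken from the sample titles: WT LSK and KO LSK with 2 libraries each, and WT LSC, KO LSC, Veh LSC and MCP LSC with 3 each. The source field of the drug samples reads LSK where their titles read LSC, and the titles were followed. The labels do not say whether replicates are separate animals, so the p-values may measure technical spread.

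The deposited values are RPKM, reads per kilobase and 1e+06 mapped reads, which was inferred from the values, since the labels do not name the unit or say whether reads or fragments were counted. Per the labels, the authors mapped to GRCm38, also called mm10; the aligner, counting tool and annotation are not given in the sources used here. The CD93 table held 26595 features with a lowest value of 0.003 and that of the drug experiment 36930 features with a lowest value of 0.001, which stand for no signal. Gene names turned into dates (25 in the CD93 experiment and 27 in the drug experiment) were kept as features under those names and matched to no list, and features that shared a name (454 and 90) were kept apart. Of all features 9548 and 14059 were at the lowest value in every library, which the filter removed. Column totals were 828673 to 1360552.

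No counts were used, so depth was estimated from the values: in single-exon genes low values should be whole multiples of the value of 1 read, and a periodogram gave such a step in 13 libraries. Within 0.1 of a whole multiple were 76.7% to 92.9% of the low values in the CD93 experiment, 54.8% to 64.1% in MCP and 35.5% to 44.4% in Veh, so the Veh depths are the least certain. It found none in the 3 KO LSC libraries. A first estimator had picked fractions of the step and was replaced after its results were seen. The estimates have no error attached, and no counting interval was computed from them.

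Values were analysed as log2(value + 1) with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with an intensity trend in the variance prior and 1 mean per group. The 10 libraries of the CD93 experiment shared 1 model and the drug experiment had its own. Genes with at least 1 RPKM in at least 2 libraries were tested, 13485 and 14005, with two-sided p-values adjusted by Benjamini-Hochberg over all tested genes of a comparison and a threshold of 0.05. The plan assumed counts and named this model for normalised values. A log2 difference of a gene at the lowest value in 1 group depends on the added 1, so levels are given for such genes and no fold. The comparisons were KO against WT in LSCs and in LSK cells, LSC against LSK in WT and in KO, the difference between these effects, and MCP against Veh.

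Gene lists, 36 in number, were written before the data were examined, as were the comparisons, the first set of alternatives and the rule for naming genes. Lists with at least 5 tested genes (34) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks whether a list moves on balance one way and does not compare it with other genes. Of the list entries 891 were matched to the CD93 experiment by symbol, 19 by synonym and 13 by mitochondrial name, and 2 were not listed; in the drug experiment these numbers were 899, 8, 13 and 5. Named genes were Cd93, then in the LSC genotype comparison, the WT leukemia comparison and the drug comparison the 10 largest changes each way, and in the others the 5 largest, among genes that passed, averaged at least 5 RPKM in the higher group and had groups that did not overlap. If fewer passed, all that passed were named with the 5 smallest p-values; unnamed models, pseudogenes and gene segments were left out. Up to 4 members with the smallest p were named for each list that passed camera or was a target of the study, and genes counted in a list may be named as its members. Single-gene results of a few genes that the rule names are not reported here. Gene positions are from GENCODE release M21 on GRCm38.

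The alternatives chosen in advance were quantile normalization, no filter, a pseudocount of 0.1, the replicate number as a block, only the compared groups in the model, and leaving out each library in turn; a filter on a mean of 5 RPKM, library weights, a crossed block and thinning of the Veh libraries were added after the data were seen. Tests that need counts (edgeR, DESeq2, voom) were planned and not run. The model was tested on simulated data with 50 changed genes of each size: at a log2 difference of 2 it recovered 88% in the drug comparison, 12% to 24% in the comparisons of 2 groups in the CD93 experiment and 0% for the interaction, with 0 to 7 unchanged genes called. Unchanged simulated genes had the same mean and spread in all libraries, and no values were held at a lowest value. These rates therefore need not hold for the real data, where many genes are at that value and the spread differs between groups. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.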

Results

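RNA sequencing profiled blood-forming stem and progenitor cells of mice with and without Cd93, before and after they became leukemic, and leukemic stem cells of mice given metoclopramide. Naive LSK cells are the lineage-negative, Sca-1-positive, c-Kit-positive bone marrow fraction that contains hematopoietic stem cells (HSCs). Leukemia stem cells (LSCs) were sorted from mice with chronic myeloid leukemia (CML), made by transplanting LSK cells that carried the fusion oncogene BCR-ABL1 together with green fluorescent protein. Wild-type (WT) and CD93-deficient (KO) LSK cells gave 2 libraries each, and WT and KO LSCs gave 3 libraries each. A second experiment had LSCs from WT CML mice treated with metoclopramide (MCP), a dopamine receptor antagonist given at 10 mg/kg, or with vehicle (Veh), 3 libraries each, which makes 16 libraries in all. The series title links the drug to CD93 and to the self-renewal of CML stem cells, so the comparisons ask which genes change with loss of Cd93 in naive and in leukemic cells, with leukemia, and with the drug.

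Cd93 (GRCm38 chromosome 2, 148436640 to 148443563, minus strand, protein-coding) encodes a surface receptor of stem, myeloid and endothelial cells. It measured 5.34 and 22.9 RPKM in the WT LSK libraries and 1.01 and 2.10 in the KO LSK libraries. WT LSC libraries 1 and 2 listed it at 0.003, the lowest value of that experiment, and library 3 at 5.74. KO LSC libraries 1 and 3 listed it at 0.003, while KO LSC library 2 had 44.3, above each of the other 9 libraries of that experiment. Cd93 did not pass the test in any comparison (adjusted p = 1 for KO against WT in LSK cells and 0.938 in LSCs, limma, two-sided), and the labels do not say which part of the gene was deleted. In the drug experiment Cd93 was 23.0 ± 2.86 RPKM (mean ± SD, n = 3) with vehicle and 18.1 ± 3.01 with MCP, a log2 difference of −0.33 (SE 0.16, adjusted p = 0.264).

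Ly6a and Kit, which encode the markers used to sort LSK cells, were lower in the LSC than in the LSK libraries of the CD93 experiment, apart from Kit in WT LSC library 2. Kit (c-Kit) was 14.2 to 99.3 RPKM in the LSK libraries and 0.221, 16.8 and 2.63 in WT LSCs, and was listed at 0.003 in all 3 KO LSC libraries. Ly6a (Sca-1) was 529 to 790.4 in LSK cells and no higher than 5.41 in any LSC library of that experiment. Features above the lowest value numbered 14865 and 14839 in WT LSK, 14906 and 14279 in KO LSK, 7956, 6867 and 5525 in WT LSC, and 2967, 2310 and 1230 in KO LSC libraries 1 to 3. Of 37 oxidative phosphorylation genes, which most cells express, 10, 11 and 27 were at that lowest value in KO LSC libraries 1 to 3, against 2, 3 and 2 in WT LSC and 0 in each LSK library. In the drug experiment 19554, 19839 and 20014 features were above the lowest value in Veh and 16447, 15587 and 15695 in MCP. Depth estimated from the spacing of low values was 5.8 M and 7.4 M reads in WT LSK, 7.7 and 5.4 in KO LSK, 3.1, 2.7 and 3.2 in WT LSC, 12.8, 18.5 and 16.7 in Veh and 8.5, 4.1 and 5.7 in MCP, and no estimate was possible for KO LSC. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.459 to 0.541 between KO LSC libraries and 0.669 to 0.728 between WT LSC libraries. They were 0.926 and 0.938 between the paired libraries of WT LSK and of KO LSK, 0.979 to 0.980 within Veh and 0.933 to 0.943 within MCP.

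**Figure D1:**
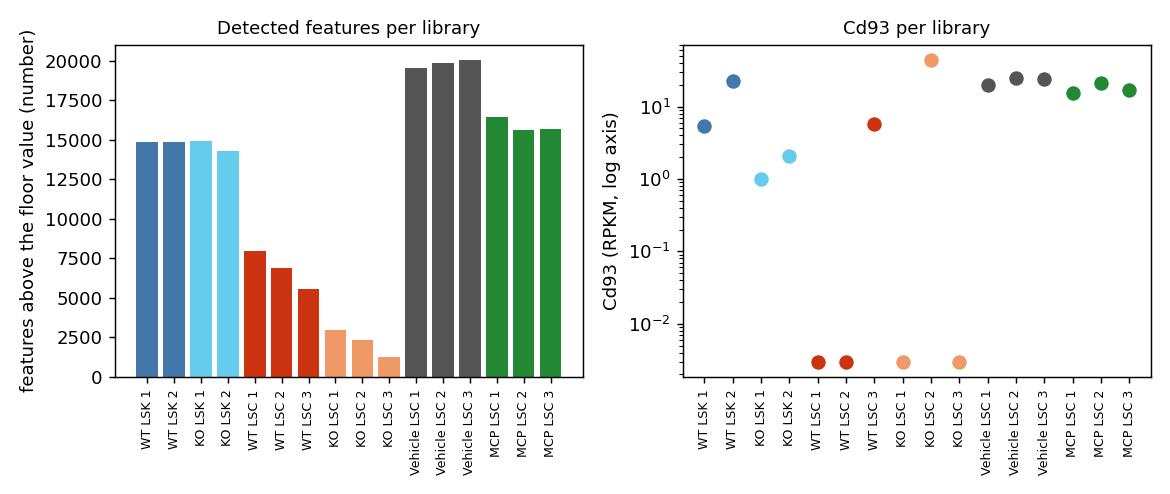
Number of features above the lowest listed value (bars, axis from 0) and Cd93 in RPKM on a log axis (points) for each of the 16 libraries, by group. The 3 KO LSC libraries have the fewest features, and Cd93 is highest in KO LSC library 2.

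Jund, Fosb, Btg2, Junb and Meis1 were lower in KO than in WT LSCs. Jund (chromosome 8, 70698949 to 70700616, plus strand), a subunit of the AP-1 transcription factor, fell from 259, 85.1 and 133 RPKM in the 3 WT LSC libraries to 2.70, 0.003 and 0.003 in the KO LSC libraries (adjusted p = 0.00142). Fosb, Btg2 and Junb were listed at 0.003 in all 3 KO LSC libraries and averaged 48.1 ± 32.5, 219 ± 188 and 62.9 ± 64.6 RPKM (SD, n = 3) in WT LSCs, with adjusted p of 0.00275, 0.0038 and 0.00508. These 4 genes were the members of the immediate-early list that passed, out of 18 tested, all lower in KO, and 6 fell when adjusted over the list alone. The list's median log2 difference was −2.94 against −0.77 over all tested genes, with camera adjusted p = 0.0174, and adjusted p = 0.88 with an estimated correlation. Meis1, a transcription factor of HSCs and leukemia, was listed at 0.003 in the KO LSC libraries against 14.5, 34.9 and 27.1 in WT LSCs (adjusted p = 0.00161).

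Rps9, Atpif1, Mrps18c and Ndufa7 were higher in KO than in WT LSCs, and H2afv, Tspo and Ndufa11 lower. Rps9 (chromosome 7, 3703993 to 3706897, plus strand), a ribosomal protein gene, rose from 5442 ± 972 to 14290 ± 2531 RPKM (log2 1.39, SE 0.32, adjusted p = 0.0347). The mitochondrial genes Atpif1, Mrps18c and Ndufa7 rose by log2 1.62 (SE 0.33), 2.86 (SE 0.60) and 2.17 (SE 0.54), with adjusted p of 0.0201, 0.0227 and 0.0492. Sri, Nup85, Hnrnpc and Eef1a1 rose by log2 3.49, 3.17, 2.69 and 2.54, and the remaining 2 of the 10 higher genes were unnamed gene models. At similar column totals, the median of values above the lowest was 65.4 to 144 RPKM in KO LSC libraries and 16.4 to 31.7 in WT LSC. These rises therefore cannot be told apart from a similar total shared by fewer features. Among the lower genes, H2afv (a histone H2A variant), Dctpp1, Ndufa11, Ndufaf2, Dad1, Rpp21, S100a6 and Denr were listed at 0.003 in all 3 KO LSC libraries and averaged 383 to 747 RPKM in WT LSCs, with adjusted p from 0.000498 to 0.0007. Tspo, a mitochondrial membrane protein gene (chromosome 15, 83563592 to 83574203, plus strand), was at 1433, 442 and 962 in WT LSCs and 0.003, 0.003 and 1.45 in KO LSCs, and Gadd45gip1 at 841, 317 and 795 against 0.003, 0.003 and 0.553. Parp14, Kif15, Guf1, Sp140 and Pgp, with adjusted p = 0.000498 each, were likewise at 0.003 in every KO LSC library. S100a8, a neutrophil protein gene, was lower in KO than in WT LSCs (log2 −1.75, SE 0.42, adjusted p = 0.0395).

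In all, 10 genes rose and 1178 fell of 13485 tested, and 896 of the lower genes were at the lowest value in all 3 KO LSC libraries, the libraries with the fewest features. Under quantile scaling 562 rose and 745 fell, 688 of the 1188 calls passed in the same direction and 19 took the opposite sign. With the replicate number as a block 717 genes passed. All 1188 had groups that did not overlap, as had 1975 of the tested genes, where chance gives at most 10%. The share by chance is lower here, since 3953 tested genes were at the lowest value in all 6 LSC libraries and cannot separate. Without WT LSC library 3 the count was 2065, and without KO LSC library 2, the library with 44.3 RPKM of Cd93, it was 1205. The higher genes numbered 48 without KO LSC library 1, 33 without KO LSC library 3, and 5 and 4 without WT LSC libraries 1 and 2. Sri passed without each library in turn, while each of the other 7 named higher genes lost its call in at least 1 such fit. With library weights 1029 genes fell and every higher call ended, Sri (log2 3.52, adjusted p = 1) and Rps9 (log2 1.46, adjusted p = 0.816) among them. Cytosolic ribosomal protein genes had a median log2 difference of 0.16 over 36 members, camera adjusted p = 2.69e-05 upward and adjusted p = 0.88 with an estimated correlation, but the median was −0.34 under quantile scaling, so no direction is given. Rps9 was their sole member to pass, and 0 passed when adjusted over the list alone (limma, 2843 genes at unadjusted p under 0.05 in the whole comparison). These were the 2 of 34 lists that passed camera. Under quantile scaling the MYC and ribosome biogenesis, oxidative phosphorylation and mitochondrially encoded genes also passed downward (adjusted p = 0.0261, 0.0496 and 0.0496) and T and NK cell markers upward (adjusted p = 0.0313). The latter is not read as a rise, since without this scaling 2 of the 30 markers were positive and 10 negative, with a median of 0. Genes tied at the lowest value of a library take the same value under this scaling. The list's median there, 0.474, was also that of the HSC, Notch and dendritic cell lists. Of the 15 tested genes of CD93's family and its partners, 0 passed (limma), with a median of 0.00 and camera adjusted p = 0.261.

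In naive LSK cells, Socs1, Lta and Igfbp7 were higher in KO than in WT, and Wfdc2, Mmrn1 and Ifit1 lower. Socs1 (chromosome 16, 10782240 to 10785536, minus strand), a feedback inhibitor of JAK-STAT signalling, rose from 2.96 and 1.27 RPKM in WT to 27.3 and 18.8 in KO LSK cells (adjusted p = 0.00455). The cytokine gene Lta and the kinase gene Pim3, like Socs1 members of the STAT5 target list, also rose, and these 3 of 16 tested passed both over all genes and adjusted over the list alone, though the list's median was 0.04 and its camera adjusted p was 0.215. Igfbp7, a secreted CD93 ligand, rose from 0.771 and 0.003 to 11.5 and 6.61 (adjusted p = 0.00572). Fcer1a and Lta were listed at 0.003 in both WT LSK libraries and measured 4.14 and 7.84, and 3.84 and 7.88, in KO LSK. Wfdc2 (chromosome 2, 164562413 to 164568510, plus strand) fell from 38.7 and 22.4 to 3.47 and 0.003, and Mmrn1, a platelet adhesion protein gene counted among CD93's family and partners, from 3.74 and 14.3 to 0.003 in both KO libraries. Ttpal, Gramd1c and Ifit1 also fell (adjusted p = 0.0189, 0.00184 and 0.0464).

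As a list, type I interferon response genes were lower in KO LSK cells by camera, with a median log2 difference of −0.76 over 33 genes, 31 of them negative, against −0.11 over all genes (camera adjusted p = 0.0014). With an estimated correlation this list and the 4 that follow had adjusted p = 0.586. Ifit1 was the member that passed, with or without the other genes in the adjustment, so 1 passed when adjusted over the list alone. Cholesterol and fatty acid synthesis genes had a median of −0.66 (adjusted p = 0.0014) with 0 of 33 passing by limma, also when adjusted over the list alone. Megakaryocyte and platelet markers had a median of −0.54 (adjusted p = 0.00468), where Itgb3 and Mmrn1 passed and 4 passed when adjusted over the list alone. T and NK cell markers had a median of 0.18 (adjusted p = 0.0394), and Thy1 rose from 4.93 and 4.14 to 12.8 and 10.6 RPKM, the 1 member to pass in either adjustment. All 36 cytosolic ribosomal protein genes were higher in KO, by a median of 0.59 (adjusted p = 4.76e-05), though 0 passed by limma in either adjustment. Each of the 5 lists kept its sign under quantile scaling. Of the 15 tested genes of CD93's family and partners, Igfbp7 rose and Mmrn1 fell, and 1 rose and 2 fell when adjusted over the list alone (median 0.17, camera adjusted p = 0.681).

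Of 13485 tested genes 110 rose and 137 fell in KO LSK cells, and 234 of these 247 were at the lowest value in all 6 LSC libraries, so their error was estimated with 6 identical values. With a model of the 4 LSK libraries alone 0 genes passed by limma (772 at unadjusted p under 0.05, against 1173 in the model of 10 libraries), and with the replicate number as a block 0 passed as well (limma, 967 at unadjusted p under 0.05). Under quantile scaling 11 rose and 4 fell. With genes averaging at least 5 RPKM 1 passed, the immunoglobulin gene segment Ighv1-80, named after its values were seen, at 2.19 ± 1.44 RPKM in WT and 116 ± 16.3 in KO LSK (n = 2). With WT LSK library 1 left out 264 rose and 395 fell, and with WT LSK library 2 left out 251 rose and 106 fell. These numbers were 176 and 767 without KO LSK library 1, and 212 and 313 without KO LSK library 2. Ifit1 lost its call without WT LSK library 2 (adjusted p = 0.156) and Wfdc2 without WT LSK library 1 (adjusted p = 0.0604). Leaving out an LSK library leaves 1 in its group, so such fits take that group's spread from the other groups. Socs1, Thy1 and Ttpal passed in each of these fits. For Socs1 and Ttpal, at 0.003 in all 6 LSC libraries, this is no support, since that spread comes largely from identical values. Lta, Igfbp7, Fcer1a, Gramd1c, Itgb3 and Mmrn1 could be tested only in the 2 such fits that left out a library of the group where they were low. They passed there, but those fits could hardly end a call, because the higher group stayed whole.

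Between naive WT LSK cells and WT LSCs, S100a8, S100a9 and Ctsg rose and HSC genes such as Procr and Esam fell. S100a8 (chromosome 3, 90668978 to 90670035, plus strand), a neutrophil calcium-binding protein gene, averaged 1866 ± 1302 RPKM in WT LSK (n = 2) and 46438 ± 11715 in WT LSCs (n = 3), a log2 difference of 4.81 (SE 0.47, adjusted p = 6.89e-05), and S100a9 rose by 4.82 (SE 0.75). The granule protease genes Ctsg (chromosome 14, 56099881 to 56102574, minus strand), Elane and Prtn3 rose by log2 4.38, 3.18 and 2.88 to 7103 ± 1678, 9335 ± 1549.8 and 6341 ± 1099.6 RPKM. Apoe and the complement genes C1qb and C1qc, of macrophages, rose by 3.20, 2.95 and 2.47. Marcks, Cdv3, Kcnk12, Dapk3, Rnr1, Arglu1, Pram1 and Prg3 were the remaining genes with the largest increases, of log2 4.64 to 7.90. The HSC genes Procr (chromosome 2, 155751117 to 155755471, plus strand), Esam, Myct1 and Sult1a1 were listed at 0.003 in all 3 WT LSC libraries, against 93.5 ± 11.3, 60.4 ± 9.06, 107 ± 27.4 and 11.8 ± 0.141 RPKM in WT LSK. Cd81, Egfl7, Tspan4, Mrpl13, Brk1, Shisa5 and Pts were also at 0.003 in the 3 WT LSC libraries and averaged 343 to 514 in WT LSK. Myl10, Serinc3 and Ccl4 fell to 1.97 ± 2.21, 4.06 ± 7.03 and 1.48 ± 2.55.

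HSC genes were lower as a list: 27 of 32 tested genes fell, 29 when adjusted over the list alone, with a median log2 difference of −3.82 against −1.94 over all genes (camera adjusted p = 0.000299, and 0.0889 with an estimated correlation). Cholesterol and fatty acid synthesis genes such as Nsdhl, Mvk, Elovl6 and Insig2 had a median of −4.43, and 24 of 33 fell, 26 when adjusted over the list alone (adjusted p = 0.00245, 0.461 with an estimated correlation). Notch pathway genes such as Mfng, Dtx2, Jag2 and Maml2 had a median of −2.82, and 12 of 19 fell, 15 when adjusted over the list alone (adjusted p = 0.0499, 0.239 with an estimated correlation), a call that ended under quantile scaling (median −0.09, adjusted p = 0.473) and with the replicate number as a block (adjusted p = 0.0507). Neutrophil markers had a median of 1.03, and S100a8, S100a9 and Camp rose while Padi4 fell, the same 3 and 1 when adjusted over the list alone (adjusted p = 5.82e-06, 0.167 with an estimated correlation). Mitochondrially encoded genes had a median of 1.66 (adjusted p = 5.01e-09, 0.221 with an estimated correlation), where ND1, ND4, ATP6 and ND2 passed in either adjustment, though ATP6 changed sign under quantile scaling. Cytosolic ribosomal protein genes had a median of 0.71 (adjusted p = 2.15e-13, 0.231 with an estimated correlation), where Rps15, Rpl23, Rps24, Rpl37 and Rps20 passed and 1 passed when adjusted over the list alone. Under quantile scaling neither of these 2 lists passed (adjusted p = 0.534 and 0.304).

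In 4 further lists the camera test was upward while the median was negative. Camera compares test statistics, which weigh each difference by its error, and not the differences themselves. The medians of these 4 lists lay above the −1.94 over all genes. Myeloid progenitor granule genes had a median of −1.27 (adjusted p = 3.59e-05, 0.0682 with an estimated correlation), with 6 higher and 4 lower, Irf8, Lyz1, Lyz2 and Rab32, and 6 and 3 when adjusted over the list alone. Monocyte and macrophage markers had a median of −0.12 (adjusted p = 8.12e-05, 0.231 with an estimated correlation), with Apoe, C1qb and C1qc higher and 3 lower, Cx3cr1 and Clec4a1 among them, the same numbers when adjusted over the list alone. Mast cell, basophil and eosinophil markers had a median of −0.02 (adjusted p = 0.00347, 0.167 with an estimated correlation), with Prg3 higher and Il4 lower in either adjustment. Under quantile scaling the medians of these 3 lists were positive, at 0.79, 1.27 and 1.25, and the granule list no longer passed (adjusted p = 0.633). Oxidative phosphorylation genes had a median of −0.48 (adjusted p = 0.00347, 0.461 with an estimated correlation), with Sdhd, Uqcrfs1, Sdhc, Sdha and Atp5b lower and 4 when adjusted over the list alone, and under quantile scaling the list test was downward (adjusted p = 0.07). CD93's family and partners had a median of −1.08 (camera adjusted p = 0.282) and 0.58 under quantile scaling, with C1qb and C1qc higher and Cblb, Clec14a, Dag1, Gipc1 and Mmrn1 lower in either adjustment.

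Of 13485 genes 196 rose and 5709 fell between WT LSK and WT LSC, and 3467 of the lower genes were at the lowest value in all 3 WT LSC libraries, which had 5525 to 7956 features above it against 14839 and 14865 in WT LSK. Under quantile scaling 1351 rose and 1568 fell, and 1900 of the 5905 calls took the opposite sign. For genes tied at the lowest value this need not be a change in the listed values. With library weights 70 rose and 5360 fell. The higher genes numbered 75 without WT LSK library 2 and 322 without WT LSC library 3. The named genes C1qc, ND1, ND4 and Sdha lost their calls without WT LSK library 2 (adjusted p = 0.0736, 0.0798, 0.101 and 0.0759), and ATP6, Cdv3, Dapk3, Marcks, ND2, Pram1, Rpl37 and Rps24 without that library and at least 1 other in turn.

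Camp and Ctsg were higher and HSC genes such as Procr lower in KO LSCs than in KO LSK cells. Camp (chromosome 9, 109847379 to 109849617, minus strand), a neutrophil antimicrobial peptide gene, rose from 409.7 ± 330.5 RPKM (n = 2) to 15296 ± 5191 (n = 3), a log2 difference of 5.43 (SE 0.74, adjusted p = 0.000438). Ctsg rose from 288 ± 92.3 to 9768 ± 4134 (log2 5.03, SE 0.46), and C3, Man2b1 and Clec4a2 rose by 4.94 to 5.28. Cmtm7, Ramp1, Ptprcap, Cnbp and Myl10 averaged 1371 to 2350.0 RPKM in KO LSK and were listed at 0.003 in all 3 KO LSC libraries. So were Procr, Sult1a1, Erg and Myct1, and of 32 HSC genes 28 fell, 29 when adjusted over the list alone, with a median of −4.02 against −3.06 over all genes (camera adjusted p = 0.0046). This list call ended with an estimated correlation (adjusted p = 0.126) and under quantile scaling (median −0.49, adjusted p = 0.282). In all 76 genes rose and 8315 fell, and 7455 of the lower genes were at the lowest value in all 3 KO LSC libraries, which had 1230 to 2967 features above it against 14279 and 14906 in KO LSK. Of the 76 higher genes 38 were among the 196 that rose in WT, more than independent calls would share. The median of values above the lowest was 65.4 to 144 RPKM in KO LSC libraries and 11.2 to 12.9 in KO LSK. Rises in KO LSCs therefore cannot be told apart from a similar total shared by fewer features. Under quantile scaling 2013 rose and 1755 fell, and 3372 of the 8391 calls took the opposite sign. For genes tied at the lowest value this need not be a change in the listed values. With library weights 7823 genes fell and every higher call ended, Camp (log2 5.77, adjusted p = 0.245) and Ctsg (log2 5.08, adjusted p = 0.41) among them. The higher genes numbered 34 and 47 without KO LSK libraries 1 and 2, and 122 and 138 without KO LSC libraries 1 and 3. Clec4a2 lost its call without KO LSK library 2 (adjusted p = 0.0712).

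**Figure D2:**
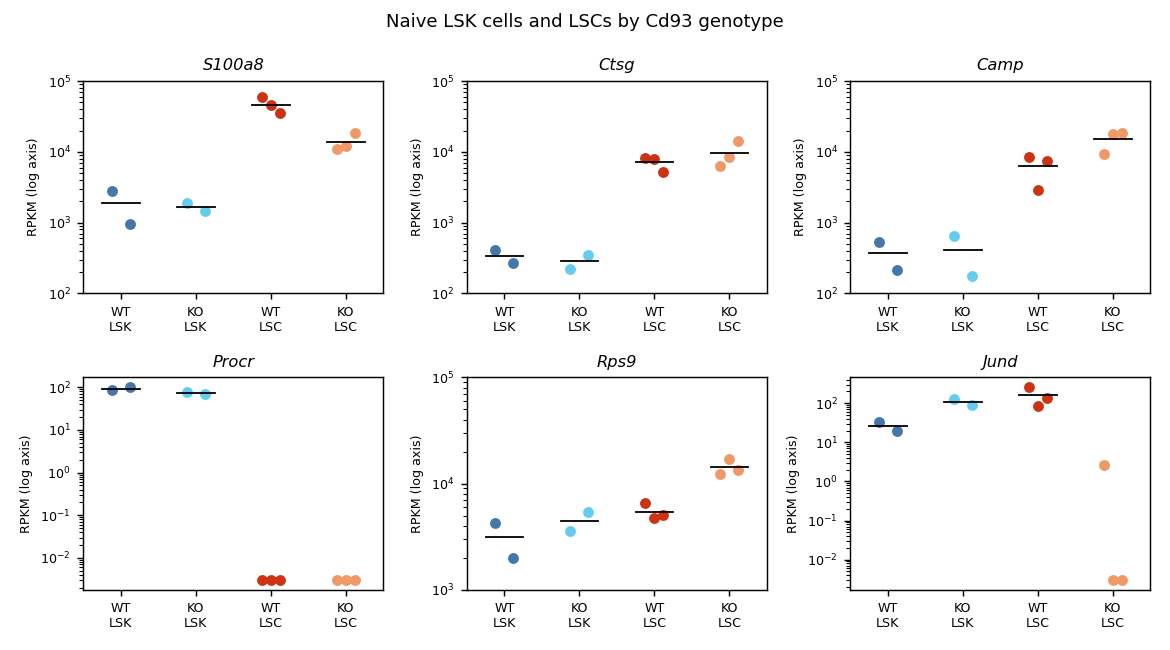
S100a8, Ctsg, Camp, Procr, Rps9 and Jund in RPKM on a log axis for WT LSK, KO LSK, WT LSC and KO LSC. Points are libraries, and a line marks the mean where no library of the group is at the lowest value; the granule genes are high and Procr is at 0.003 in all 6 LSC libraries, while Jund is low in KO LSC.

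Granule and neutrophil lists were again upward in KO LSCs by camera over negative medians. Myeloid progenitor granule genes had a median of −2.54 (camera adjusted p = 3.02e-06, 0.0405 with an estimated correlation), with Ctsg, Elane, Hp, Mpo and Prtn3 higher and 9 lower, Irf8 and Rab32 among them, the same numbers when adjusted over the list alone. Neutrophil markers had a median of −1.09 (adjusted p = 7.41e-09, 0.126 with an estimated correlation), with Camp, S100a8 and S100a9 higher and Ngp and Padi4 lower, 3 and 1 when adjusted over the list alone. Monocyte and macrophage markers had a median of −1.31 (adjusted p = 2.16e-05, 0.208 with an estimated correlation), with Apoe and C1qb higher and 5 lower, Axl, Ctsb, Cx3cr1 and Slc40a1 among them, the same numbers when adjusted over the list alone. Mast cell, basophil and eosinophil markers had a median of −2.30 (adjusted p = 0.0479, 0.266 with an estimated correlation), with Cyp11a1, Fcer1a, Il4, Ms4a2 and Prg3 lower and 3 when adjusted over the list alone. CD93's family and partners had a median of −1.49 (adjusted p = 0.0342, 0.382 with an estimated correlation), with C1qb higher and Cblb, Clec14a, Dag1, Igfbp7 and Thbd lower in either adjustment. Under quantile scaling the medians of these 5 lists were 0.47, 1.11, 1.14, 0.57 and 0.82, the first 4 lists no longer passed (adjusted p = 0.972, 0.203, 0.513 and 0.216), and single-gene differences of Cx3cr1, Fcer1a, Prg3, Ms4a2, Igfbp7, Clec14a, Dag1 and Cblb turned positive. Fcer1a and Prg3 were at 0.003 in every KO LSC library, so their positive differences come from how this scaling treats tied genes and are not rises. Oxidative phosphorylation genes had a median of −3.98 with an upward test (adjusted p = 0.000641, 0.328 with an estimated correlation), with Ndufb3 and Uqcrq higher and 7 lower, 1 and 6 when adjusted over the list alone. Under quantile scaling this list passed in the opposite direction, downward (median −3.18, camera adjusted p = 0.00122). Its median without this scaling was also below the −3.06 over all genes, so the upward test is not read as a smaller fall. Ribosomal protein genes had a median of 0.34 (adjusted p = 1.64e-22, 0.126 with an estimated correlation), with Rps9, Rps18, Rpl23 and Rpl37 higher and 1 lower, 2 and 0 when adjusted over the list alone. Mitochondrially encoded genes had a median of 0.36 (adjusted p = 5.43e-12, 0.126 with an estimated correlation), with CYTB, COX1 and ND2 higher and ATP8 lower, 1 and 1 when adjusted over the list alone. Both medians turned negative under quantile scaling, at −0.20 and −0.06 (adjusted p = 0.377 and 0.513). Without KO LSK library 1, Rpl23, CYTB, COX1, ND2, Dag1 and Cblb lost their calls (adjusted p = 0.0521, 0.0905, 0.132, 0.206, 0.0626 and 0.0657). Without KO LSK library 2, S100a9, Prg3, COX1 and Cblb lost theirs (adjusted p = 0.0917, 0.0741, 0.0622 and 0.0522). COX1 also lost it without KO LSC library 1 or 3 (adjusted p = 0.0692 and 0.0612), and Ms4a2 in all 5 leave-one-out fits (adjusted p from 0.0552 to 0.166).

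The difference between KO and WT was not the same in LSCs and LSK cells by the interaction test for Jund, Pgp, H2afv and Tspo, among others. Genotype and the number of features go together in the LSC libraries, so this is not read as an effect of Cd93 loss. Jund was 110.5 ± 25.1 RPKM in KO LSK and 26.4 ± 8.99 in WT LSK (n = 2), the opposite order to LSCs, though this LSK difference did not itself pass (adjusted p = 0.681). Its interaction passed (adjusted p = 0.00975). Pgp, a phosphatase gene (chromosome 17, 24470392 to 24473110, plus strand), measured 124.5 and 88.1 in KO LSK against 29.4 and 24.0 in WT LSK, which did not pass (adjusted p = 0.431), but was listed at 0.003 in all 3 KO LSC libraries against 384, 227 and 429 in WT LSCs (interaction adjusted p = 0.00764). H2afv, Dctpp1, Tspo and Gadd45gip1 did not differ by the test between the LSK groups (adjusted p = 1) and were at or near the lowest value in KO LSCs (interaction adjusted p = 0.00764 to 0.00802). Wfdc2, Ttpal, Gramd1c and Fchsd1 were at 0.003 in all 6 LSC libraries, and Mmrn1 in at least the 3 KO LSC libraries, so their interaction (adjusted p = 0.00764 to 0.03) carries the difference between the LSK groups. Immediate-early genes had a median interaction of −2.92 over 18 genes against −0.78 over all genes (camera adjusted p = 0.0143, 0.99 with an estimated correlation), where Jund passed and 5 passed when adjusted over the list alone. Cholesterol and fatty acid synthesis genes had a median of 0.47 (adjusted p = 0.00647, 0.99 with an estimated correlation), while Fdps, the 1 member of 33 to pass in either adjustment, was negative. In LSCs this list's median genotype difference was 0, with 4 members positive and 12 negative. The interactions of Scd2, Sc4mol and Elovl6 (1.84, 1.95 and 0.91) were their LSK differences with the sign reversed. The list's positive interaction is therefore not read as an effect in LSCs. CD93's family and partners had a median of −0.45 (camera adjusted p = 0.763) and 0.24 under quantile scaling, and Igfbp7 (negative) and Mmrn1 (positive) passed in either adjustment. Igfbp7 was at 0.003 in all 6 LSC libraries, so its interaction (−2.87) is its LSK difference with the sign reversed.

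Of 13485 genes 126 had a positive and 694 a negative interaction, and 719 of these 820 were at the lowest value in all 3 KO LSC libraries. Under quantile scaling 96 were positive and 54 negative, 131 of the 820 calls passed in the same direction and 10 took the opposite sign. With library weights 233 were positive and 355 negative. With the replicate number as a block 0 passed (limma, 1778 at unadjusted p under 0.05). With KO LSK library 1 left out 637 were positive and 603 negative. These numbers were 308 and 661 without WT LSK library 1, and 277 and 609 without KO LSK library 2. They were 99 and 1083 without WT LSC library 2, and 110 and 1448 without WT LSC library 3. They were 63 and 649 without KO LSC library 2, and 53 and 438 without KO LSC library 3. Fchsd1, Mmrn1, Ttpal and Wfdc2 each lost their calls without KO LSC library 2 (adjusted p = 0.0608, 0.0544, 0.0547 and 0.0638), without KO LSC library 3 (adjusted p = 0.0753, 0.0675, 0.0681 and 0.0781) and in other leave-one-out fits.

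With metoclopramide, Elane, Ctsg, Prtn3 and Mpo rose and Fos, Egr1, Meis1 and Hlf fell in LSCs. Elane (chromosome 10, 79886247 to 79888215, plus strand), which encodes neutrophil elastase, rose from 489 ± 31.5 RPKM in Veh to 899 ± 30.1 in MCP (n = 3 each), a log2 difference of 0.88 (SE 0.07, adjusted p = 0.00286). Ctsg, Prtn3 and Mpo rose by 0.60, 0.67 and 0.49 (SE 0.06, 0.07 and 0.06), Mpo from 1965 ± 73.9 to 2753 ± 82.3. Fos (chromosome 12, 85473890 to 85477273, plus strand), an AP-1 subunit, fell from 367 ± 3.93 to 187 ± 9.07 (log2 −0.97, SE 0.06, adjusted p = 0.00117), and Egr1 and Dusp1 changed by log2 −0.78 and −0.60. Meis1 (chromosome 11, 18879817 to 19018985, minus strand) fell from 48.8 ± 4.09 to 22.8 ± 1.56 (log2 −1.07, SE 0.11, adjusted p = 0.00903), and the HSC transcription factor gene Hlf changed by −1.28. Klf2 and Klf4, of quiescence, changed by −1.73 and −1.48, and Myc by −0.52.

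Cpa3, Cma1 and Tpsb2 of mast cells and Cd74 of antigen presentation fell with MCP as well. Cpa3 (chromosome 3, 20215620 to 20242181, minus strand), a mast cell protease gene, fell from 114 ± 6.42 to 14.5 ± 2.56 RPKM (log2 −2.90, SE 0.14, adjusted p = 0.00033), and Cma1 (chromosome 14, 55941451 to 55944675, minus strand), which encodes chymase, from 89.8 ± 5.41 to 12.5 ± 1.40 (log2 −2.75, SE 0.12). Tpsb2 fell from 42.6, 46.0 and 36.5 to 3.30, 2.18 and 0.421, and Cd200r3 was listed at 0.001, the lowest value of that experiment, in all 3 MCP libraries against 5.90, 5.79 and 6.51. Gzmb, Lilrb4, Cyp11a1, Csf1, Lif and Tomm20 changed by log2 −2.10, −1.97, −1.85, −1.81, −2.07 and −1.75. Cd74 (chromosome 18, 60803848 to 60812652, plus strand), the invariant chain of MHC class II, fell from 53.1 ± 3.71 to 20.4 ± 4.02 (log2 −1.35, SE 0.15, adjusted p = 0.0114). The immunoglobulin genes Igkc and Igj were listed at 0.001 in all 3 MCP libraries against 47.4, 43.0 and 46.9, and 3.26, 3.92 and 5.05, in Veh. Among the higher genes, Fuom, Trem1, Commd6, Hp and S100a8 rose by 1.64, 1.38, 1.11, 0.88 and 0.79, as did the transfer RNA genes Trnaq-uug, n-Th5, n-Tk13 and n-Tg25 (log2 0.91 to 1.59), whose near-identical copies leave the source of their reads uncertain.

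**Figure D3:**
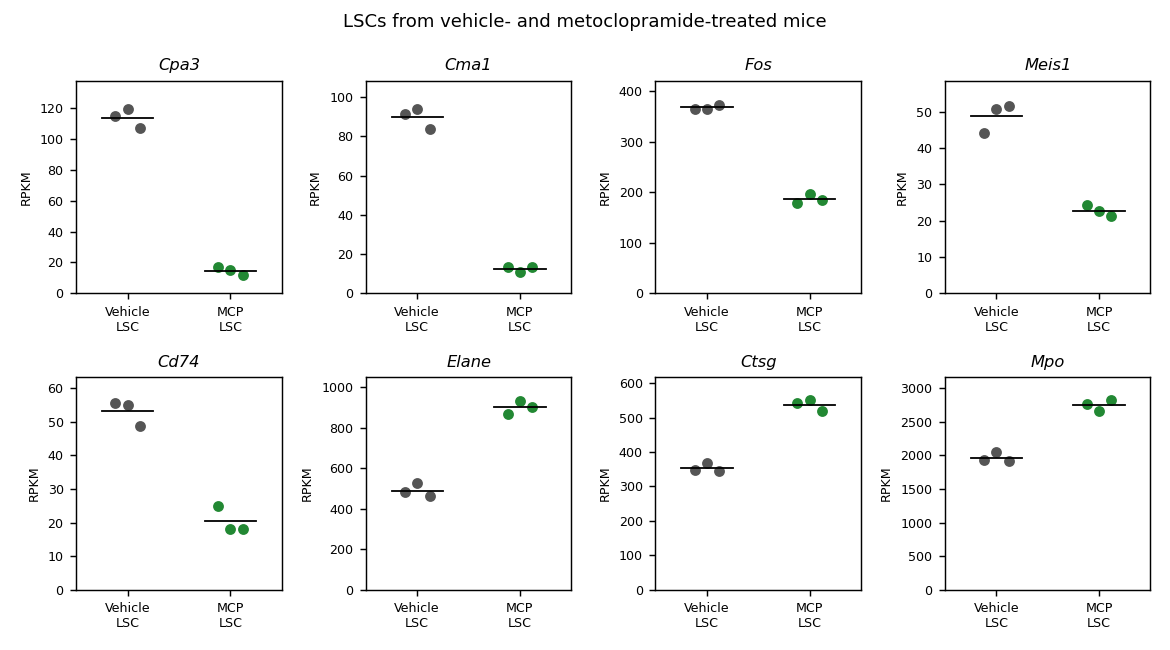
Cpa3, Cma1, Fos, Meis1, Cd74, Elane, Ctsg and Mpo in RPKM (axes from 0) in LSCs of vehicle and metoclopramide mice. Points are the 3 libraries of each group and lines their means; the first 5 genes are lower and the last 3 higher with metoclopramide in every library.

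Among gene lists, myeloid progenitor granule genes had a median log2 difference of 0.29 against −0.18 over all genes (camera adjusted p = 5.5e-13, 0.0894 with an estimated correlation), with 7 of 29 higher and Csf1r lower, and 9 and 2 when adjusted over the list alone. Cytosolic ribosomal protein genes had a median of 0.22 with all 36 positive (adjusted p = 1.06e-27, 0.159 with an estimated correlation), of which Rpl37, Rpl10a and Rps24 passed and 23 passed when adjusted over the list alone. Mitochondrially encoded genes had a median of 0.23 (adjusted p = 2.34e-12, 0.153 with an estimated correlation), with ATP8 and ND3 passing and 8 when adjusted over the list alone, but −0.07 under quantile scaling (adjusted p = 0.251), where ATP8 also turned negative. Oxidative phosphorylation genes had a median of 0.12 (adjusted p = 1.92e-10, 0.165 with an estimated correlation), with Cox6c and Ndufb9 passing and 5 when adjusted over the list alone. Neutrophil markers had a median of 0.02 (adjusted p = 0.0145, 0.224 with an estimated correlation), with S100a8 passing and 4 higher and 3 lower when adjusted over the list alone. Unfolded protein response genes had a median of −0.02 but an upward test (adjusted p = 0.0481, 0.356 with an estimated correlation), with 0 passing by limma over all genes, where 3226 had unadjusted p under 0.05, and Pdia3, Dnajb9 and Hspa5 passing when adjusted over the list alone, 3 in number. That list call ended under quantile scaling (adjusted p = 0.538) and with the replicate number as a block (adjusted p = 0.0562).

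HSC genes had a median of −0.72, and 7 of 31 fell, Meis1, Hlf and Gpr56 among them, while 19 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.39e-07, 0.0894 with an estimated correlation). Immediate-early genes had a median of −0.44, and 9 of 21 fell, 12 when adjusted over the list alone (adjusted p = 2.27e-06, 0.137 with an estimated correlation). Mast cell, basophil and eosinophil markers had a median of −1.15, and 10 of 23 fell, 14 falling and 2 rising when adjusted over the list alone (adjusted p = 2.85e-06, 0.137 with an estimated correlation). All 12 MHC class II genes were lower, by a median of −1.05 (adjusted p = 5.95e-06, 0.0894 with an estimated correlation), and Cd74, H2-DMa, H2-Eb1 and H2-Ob passed, 10 when adjusted over the list alone. Megakaryocyte and platelet markers had a median of −0.80 (adjusted p = 2.86e-05, 0.0894 with an estimated correlation), with Itga2b, F2r and Vwf lower and 14 when adjusted over the list alone. STAT5 target genes had a median of −0.52 (adjusted p = 0.000124, 0.168 with an estimated correlation), with Myc lower and 10 when adjusted over the list alone. Genes of quiescence and cell-cycle inhibition had a median of −0.40 (adjusted p = 0.00818, 0.185 with an estimated correlation), with Klf2 and Klf4 lower and 4 when adjusted over the list alone.

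CD93's family and partners had a median of −0.64 with MCP (camera adjusted p = 0.00894, 0.168 with an estimated correlation), where Msn, which encodes moesin, fell (log2 −0.59, SE 0.08, adjusted p = 0.0238) and 7 of 14 fell when adjusted over the list alone. B-lineage markers had a median of −0.70 (adjusted p = 0.0185, 0.168 with an estimated correlation), with Igkc, Igj and Ighm lower in either adjustment. NF-kB and inflammatory genes had a median of −0.40 (adjusted p = 0.0262, 0.211 with an estimated correlation), with Nfkbiz and Cxcl2 lower and Nfkbia higher, and 10 lower and 1 higher when adjusted over the list alone. Adhesion and homing genes had a median of −0.31 (adjusted p = 0.0267, 0.166 with an estimated correlation), with Itga2b and Msn lower and 10 when adjusted over the list alone. CML stem cell marker genes had a median of −0.34 (adjusted p = 0.0267, 0.168 with an estimated correlation), with Csf2rb and Cd34 lower and 7 when adjusted over the list alone. Of the 12 receptors and enzymes that metoclopramide binds, Ache was the 1 with values high enough to test, at 4.45, 3.89 and 4.06 in Veh and 3.44, 1.90 and 1.41 in MCP (adjusted p = 0.197). Drd2, its principal receptor, was listed at 0.001 in all 6 libraries, as were Drd3, Drd4, Drd5, Htr3a, Htr3b, Htr4, Chrm1, Chrm2 and Bche, and Drd1 was above that value in Veh library 1, at 0.058.

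In all 73 genes rose and 252 fell of 14005 tested, and 45 of the lower genes were at the lowest value in all 3 MCP libraries, which had an estimated 4.1 M to 8.5 M reads against 12.8 to 18.5 in Veh. Under quantile scaling 109 rose and 151 fell, 197 of the 325 calls passed in the same direction and 2 took the opposite sign. With no filter 15 rose and 214 fell. All 325 had groups that did not overlap, as had 4275 of the tested genes, where chance gives 10%. With Veh library 1 left out 2 rose and 44 fell. With Veh library 2 left out 19 rose and 60 fell, and with Veh library 3 left out 3 rose and 22 fell. With the replicate number as a block 39 genes passed. Cma1, Cpa3, Cd200r3, Igkc, Elane and Fos passed without each library in turn, while Meis1 lost its call without Veh library 3 (adjusted p = 0.0681), Cd74 without Veh library 1, 2 or 3 (adjusted p = 0.0647, 0.0506 and 0.0663), and every other gene named here as changed by the drug and refitted in this way lost it in at least 1 of the 6 leave-one-out fits.

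Whether MCP moved the same genes as loss of Cd93 in LSCs was asked last, and the relation was weak. The log2 differences of 10948 genes tested in both had a Pearson r of −0.0875 and a Spearman rho of −0.0735 across genes, which are not independent replicates, and 52.2% had the same sign. Fosb, Meis1, S100a6, Dnmt1 and Myh9 were among 22 genes that fell in both, where 19.7 would be shared by chance (Fisher's exact test, two-sided p = 0.55). Ndufa7 rose in both, 1 gene against 0.0424 by chance (Fisher's exact p = 0.0416). The 8 genes higher in KO LSCs that were tested with MCP had a median log2 difference of 0.21 there, and the 1075 lower ones a median of −0.17, against −0.18 over all genes. With genes averaging at least 10 RPKM the Pearson r was 0.012.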

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

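The tests of a wrong label on KO LSC replicate 2, of mast cells, of neutrophil RNA and of the size of differences after thinning were chosen after the results were seen, while those of random loss and of the share of calls left after thinning were written before.

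The difference between KO and WT was not the same in LSCs and LSK cells for 820 genes by the interaction test. It cannot be told apart from the low number of features in the KO LSC libraries. Among named genes the fitted interaction was −10.32 for Pgp, −9.83 for H2afv, −9.69 for Dctpp1, −9.62 for Tspo and −9.53 for Gadd45gip1. Each of these was at or near the lowest value in KO LSCs. The interaction was 3.85 for Wfdc2, 3.04 for Mmrn1, 2.85 for Ttpal, 2.82 for Gramd1c and 2.64 for Fchsd1. All were close to or at the lowest value in the LSCs, so these values mirror the LSK difference. These log2 values depend on the pseudocount and are not folds.

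Genes such as H2afv, Dctpp1 and Ndufa11 were at the lowest value in all 3 KO LSC libraries and abundant in WT LSCs, within a set of 1178 lower genes. Of 3399 genes averaging at least 20 RPKM over the LSC libraries, 77.5% of those that any KO LSC library detected were missing from another KO LSC library, against 23.0% in WT LSC and 0.501% in KO LSK. Of the 3399 genes, 707 were detected in no KO LSC library, 1264 in 1, 821 in 2 and 607 in all 3. In WT LSC 72 were in none and 2563 in all 3. Most of these abundant genes thus differed in detection between libraries labelled KO LSC, which is what random loss of transcripts would give. For the lower calls, random loss still cannot be told apart from an effect of genotype. The share of 77.5% leaves out genes that no KO LSC library detects, and 896 of the 1178 are such genes. A wrong label on KO LSC replicate 2, which has 44.3 RPKM of Cd93, was asked as a source of the lower calls. Without that library 77.9% of them passed, and their median log2 difference was −4.66 against −4.68 with all libraries. Most of the lower calls thus did not need that library, but this outcome was largely fixed in advance and does not test its label. Those 896 could hardly be lost by leaving it out, and a CD93-proficient library among the KO ones would make differences smaller. Whether its label is right stays open, as does residual transcription of the deleted gene, since the labels do not say which part of Cd93 was removed. Loss of Cd93 itself stays open, as complexity and genotype go together in these 6 libraries.

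Cpa3, Cma1, Meis1, Klf2 and 248 further genes fell with MCP, where Veh libraries were deeper. After the Veh libraries were thinned in 1 random draw to the depth of the MCP libraries, 73.4% of the lower calls still passed, between the bounds of 50% and 80% set before. The median log2 difference of all 252 was −0.95 before and after, and the 230 of known length kept a median of 100.1% of their difference (5th to 95th percentile 91.1% to 109%), so thinning did not shrink the differences. Thinning keeps the expected value of a gene, so for genes well above the lowest value this outcome was largely fixed in advance. It does not decide whether depth set the size of the differences. For which genes passed, depth cannot be told apart from the drug, because the share left lies between the bounds. The Veh depths are also weakly supported, with 35.5% to 44.4% of low single-exon values near whole multiples of 1 read. The 67 calls that ended had a median of −0.85 (median SE 0.157) before and −0.80 (0.166) after, a slightly smaller difference with a larger error that took adjusted p to 0.0502 to 0.228, so for these the call, more than the difference, depended on depth in that draw. For the mast cell part, 10 of 11 markers at 5 RPKM or more (90.9%) were lower, by a median of −1.59, led by Cpa3 at 114 against 14.5 RPKM and Cma1 at 89.8 against 12.5. None of these markers was in another list, and 5 measured at least 5 RPKM in WT LSK cells. Whether the sort kept c-Kit-positive mast cells or their progenitors is not known. Fewer mast cells or basophils in the sorted MCP samples cannot be told apart from lower expression of these genes, because the markers' fall is what raised the question. An effect of the drug on the LSCs themselves stays open, as it does for Fos, Meis1 and the granule genes.

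S100a8, S100a9, Camp and Ctsg rose between WT LSK and WT LSC, S100a8 to 46438 RPKM. RNA of neutrophils in the sorted LSCs may contribute, since 10 of 15 neutrophil markers at 5 RPKM or more (66.7%) were higher, by a median of 2.95 over the 15. Among abundant neutrophil genes, Ngp averaged 352 RPKM in WT LSCs against 208 in WT LSK, and Lcn2 622 against 42.4, neither of which passed. None of the 15 was in another list, 13 measured at least 5 RPKM in WT LSK cells, and sorting of LSK cells would remove neutrophils. Neutrophil RNA cannot be told apart from granule gene expression by the leukemic cells, because the share falls between the bounds of 50% and 80%.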

How the results depend on the processing

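A filter on a mean of 5 RPKM, library weights, a crossed block and thinned Veh libraries were tests chosen after seeing the data; the others were planned. The KO LSC libraries had 1230 to 2967 features above the lowest value and no estimate of reads, so low depth and low complexity were not separated in them. Count-based tests were not run, as no counts were used, and the limma fit without 1 LSK library takes the spread of the remaining one from the other groups. Of the settings of results that answer a comparison 74 were labelled the same, 37 moved and 1 changed sign, where counts within a set ratio were labelled the same. For single genes 600 settings ended a call, 61 added a call and 15 changed the sign of a called gene. The other 2662 were labelled the same, which may include changed signs of genes not called at first. The cause was not tested unless given.

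With the replicate number as a block, 717 genes passed for KO LSC against WT LSC, 39 for MCP, 0 for KO LSK against WT LSK (limma, 967 at unadjusted p under 0.05) and 0 for the interaction (limma, 1778). The numbers show no pairing: deviations from the group means had r of −0.0232 to 0.00348 between WT and KO LSC libraries of the same number, and −0.0282 to 0.0338 between those of different numbers. The LSK libraries, 2 per group, give a single value, −0.28 for the same number. With the KO LSK numbers exchanged, a block of equal size, 196 passed.

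Under quantile normalization 15 genes passed for KO LSK against WT LSK, 2919 and 3768 for LSC against LSK in WT and KO, and 150 for the interaction. For WT LSC against WT LSK the log2 differences changed sign for Maml2 (0.25), ATP6 (−0.47), Dag1 (0.051), Mmrn1 (0.056), Cblb (0.19) and Clec14a (0.54). For KO LSC against KO LSK they changed sign for Cx3cr1 (0.28), Fcer1a (0.30), Prg3 (0.43), Ms4a2 (0.74), Igfbp7 (0.085), Clec14a (0.78), Dag1 (0.82) and Cblb (0.94), and for MCP that of ATP8 (−0.11). Quantile normalization removes the shift of all genes by construction. It also gives all genes tied at the lowest value of a library the same value, however many they are. Fcer1a and Prg3 were listed at 0.003 in every KO LSC library and were higher in both KO LSK libraries, so their positive differences are not rises. A changed sign under this scaling need not be a change in the listed values. Further lists that passed camera under it were, for KO LSK against WT LSK, quiescence and monocyte genes upward and adhesion genes downward (adjusted p = 0.0089, 0.0299 and 0.0465), and for WT LSC against WT LSK, S-phase and glycolysis genes downward and CD93's family upward (adjusted p = 0.00882, 0.0184 and 0.0425). For KO LSC against KO LSK they were S-phase, MYC and immediate-early genes downward (adjusted p = 0.00122, 0.0365 and 0.0365), for the interaction ribosomal protein genes downward (adjusted p = 0.00859), and for MCP G2/M and MYC genes downward (adjusted p = 0.0289 and 0.023).

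For KO LSK against WT LSK, 404 genes passed with no filter, 0 with only the 2 groups in the model (limma, 772 at unadjusted p under 0.05, smallest adjusted p 0.0723), 1 with a mean of at least 5 RPKM and 469 with library weights, some of whose fits stopped before converging. With a mean of at least 5 RPKM, which leaves fewer genes, 3021 and 5396 passed for LSC against LSK in WT and KO.

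Leaving out each library in turn gave 964 to 2065 genes for KO LSC against WT LSC (2065 without WT LSC replicate 3), 4502 to 6455 and 6201 to 8416 for LSC against LSK in WT and KO, 357 to 943 for KO LSK against WT LSK (659 without WT LSK replicate 1, 943 without KO LSK replicate 1, 525 without KO LSK replicate 2), 491 to 1558 for the interaction (1240 without KO LSK replicate 1, 1558 without WT LSC replicate 3, 491 without KO LSC replicate 3) and 25 to 406 for MCP (46, 79 and 25 without Veh LSC replicates 1, 2 and 3).

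Of the gene lists, with an estimated correlation 0 passed for KO LSC against WT LSC, 0 for KO LSK against WT LSK, 0 for WT LSC against WT LSK, 1 for KO LSC against KO LSK, 0 for the interaction and 0 for MCP (camera). By fry, which does not compare a list with other genes, these numbers were 22, 0, 29, 31, 10 and 30. The correlation of MCP and CD93-loss differences was 0.0116 with a mean of at least 10 RPKM and −0.155 over the genes called in KO LSCs.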

Other observations

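The alpha-globin genes Hba-a1 and Hba-a2, chosen after their values were seen, were higher in LSCs than in LSK cells, while the erythroid list went both ways: of 24 tested markers 3 were higher and 8 lower in WT (median −1.10, camera adjusted p = 0.159) and 2 higher and 12 lower in KO (median −2.51, adjusted p = 0.342), the same numbers when adjusted over the list alone. Hba-a1 rose from 270.2 ± 155.7 RPKM in WT LSK (n = 2) to 2504 ± 794 in WT LSCs (n = 3, log2 3.28, SE 0.55, adjusted p = 0.00161), and from 202.5 ± 20.2 to 2052 ± 453.8 in KO. Hba-a2 rose from 77.0 ± 47.1 to 964 ± 371 in WT, while Hbb-b1 did not pass (adjusted p = 0.645). In the drug experiment Hba-a1 fell from 61.6 ± 4.68 to 38.0 ± 2.76 with MCP (log2 −0.68, SE 0.10, adjusted p = 0.0251) and Hbb-bs from 71.9 ± 2.90 to 51.3 ± 4.11 (adjusted p = 0.0455), where of 29 erythroid markers 1 rose and 2 fell, 2 and 5 when adjusted over the list alone.

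Members of growth and interferon lists were at low values in KO LSCs, although their lists did not pass camera apart from the MYC and ribosome biogenesis list under quantile scaling (adjusted p = 0.0261). Of the MYC and ribosome biogenesis genes, Ddx18, Ddx21, Fbl, Mybbp1a, Nolc1, Pa2g4 and Pes1 were lower in KO than in WT LSCs, 7 of 30 tested and 8 when adjusted over the list alone (camera adjusted p = 0.0746). S-phase genes that were lower were Ccne2, Clspn, Prim1, Rrm1 and Uhrf1, and G2/M genes Cdca8, Kif11, Nusap1 and Top2a, the same 5 and 4 in number when adjusted over the list alone. Interferon response genes that were lower were Gbp3, Ifih1, Oas1a, Parp14, Stat2 and Trim30a, 6 in either adjustment.

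Xist, the RNA of the inactive X chromosome, was 57.7 to 133 RPKM in 9 of the 10 libraries of the CD93 experiment and 0.144 in KO LSC replicate 3, and 170 ± 8.02 in Veh and 148 ± 7.46 in MCP. The Y-linked genes Ddx3y and Kdm5d were at the lowest value in all 16 libraries.

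Tests on other splits of the libraries were planned. The 6 LSC libraries of the CD93 experiment can be split into 3 against 3 in 10 ways, so the share of splits is never under 0.1; the real split gave 1188 genes (1 of 10 splits gave as many) and the highest other split 53. For gene lists 3 of 10 splits gave as many as the real 2, the highest other giving 3. For MCP against Veh, also 10 splits with the same limit, the real split gave 325 genes and 18 lists (1 of 10 for each) and the highest others 2 genes and 11 lists. The correlation of MCP and CD93-loss differences, −0.0875, was reached in size by 2 of 100 splits, the real one included. The highest other was 0.0978 and the median size 0.0235. The share is under the bound of 0.05 set before. It does not exclude chance, because the splits reuse the same libraries and another split gave a larger size. Among genes averaging at least 10 RPKM r was 0.0116.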
